A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

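RNA was extracted from 3 untreated and 3 SynAnt49-treated aliquots. Per the labels' protocols, ribosomal RNA was removed with a Ribo-Zero kit, strand-specific libraries were made with a NEB Ultra directional kit, and the libraries were sequenced on a HiSeq3000. The counts were deposited as whole numbers of reads per annotated gene; per the file headers, featureCounts 1.6.1 counted reads on the sense strand of each gene feature. Bowtie2, SAMtools, DESeq2 and R 3.4 are named in the submitters' processing notes, and the versions of the first 3 are not given in the sources used here. No option for reads that overlap several genes or map to several places stands in the header, so reads falling on more than 1 gene of the same strand were dropped by default, and reads from near-identical genes may be split between copies. The annotation is that of SubtiWiki, and its coordinates refer to the Bacillus subtilis 168 reference chromosome. Of 5835 rows counted, 4164 were protein-coding genes, 1584 annotated new RNA features and 87 other genes; 989 overlapped another row of the same strand at least in part, 12 of them over most of their length. Features annotated as ribosomal RNA (30), transfer RNA (86) or other structural RNA (52) have another feature type and carry no counts. Of the locus tags, 4242 matched the gene table of the reference annotation, which was used to tell protein-coding genes from other genes. Gene names were matched on the symbols and aliases of the deposited annotation.

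The authors also deposited normalized signal values, which are the counts divided by 1 DESeq2 size factor per library, computed over 12 libraries. The authors' deposited table of their own comparison gives log2 fold changes with standard errors from DESeq2, with untreated over SynAnt49 as its sign; the sign was turned for the comparison made here. The same deposited table holds the p-value of each gene and its Benjamini-Hochberg adjusted value, which the authors obtained from a fit that included libraries of other treatments, per the series design text. In each of the count and signal files, 6 columns belong to no sample described here and were not used.

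Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Rows passing the default expression filter (4423 tested, 1412 left out, 415 of the 5835 without any count) were scaled with TMM factors and fitted with the quasi-likelihood model with group as the only term. P-values were adjusted by Benjamini and Hochberg over the rows tested, with a threshold of 0.05. The common biological coefficient of variation was 0.214. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, with TMM-scaled library totals as the divisor. A library total between 5889386 and 6731713 counts puts the floor of 3 counts at 0.446 to 0.509 CPM, and this floor covers counting error only.

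Lists of genes for 36 regulons and pathways were fixed from general knowledge before the data were examined, as were the groups, the test, its alternatives and the rule for named genes. The 1023 list symbols gave 1003 list rows, because some symbols matched no row and others named the same row as another symbol of their list. Lists were tested with camera of limma 3.58.1 on log CPM with a prior count of 2, a preset correlation of 0.01 and at least 4 tested members, adjusted over the lists, and the members of each list were also adjusted over the list alone. Camera compares the genes of a list with all other genes. With the correlation estimated from the data, camera called 0 lists. That estimate rests on only 6 libraries. Even the sigma factor W list, with 52 of 54 genes higher, had an unadjusted p of 0.0738 there, and the lowest of all lists was 0.0529. This setting thus had little ability to call a list, and a call lost under it is weak evidence against that list. The preset has a limit in the other direction. Among called lists the estimated correlation ran from 0.008 (osmotic and potassium) to 0.727 (ribosomal proteins), with 0.515 for sigma factor W and 0.589 for branched-chain synthesis. Where it lies far above 0.01, list p-values at the preset may be much too small. Library medians of a list are differences of log CPM from the mean of the untreated libraries. The named genes are the 12 largest rises and 12 largest falls among protein-coding genes with a symbol, a mean of at least 20 CPM, an adjusted p below the threshold and SynAnt49 values all on 1 side of the untreated values. To these come up to 4 members with the smallest p in the direction of each called list, a fixed set of reporter genes of antibiotic stress systems whatever their values, and the 3 new RNA features with the largest change. Other genes are named only where the text says that they were chosen after their values were seen.

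The steps were tested on simulated data with the means and library sizes of these libraries. At a simulated 1.5-fold change 4.0% of 198 changed genes were recovered, at 2-fold 59.6% of 198 and at 4-fold 96.4% of 193, with 2, 11 and 10 false calls among 4351, 4353 and 4346 genes, and 0 of 36 random lists were called. Changes of 1.5-fold were therefore mostly missed in the simulation, where 198 of 4351 genes changed. The real comparison called 1948 of 4423 rows. Adjustment over genes is less strict when more genes change, so the simulated shares do not carry over to it. Genes were simulated independently of each other. The 0 random lists called therefore do not show how often lists of correlated genes are called falsely. Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a replicate block, protein-coding genes alone, thinning to equal depth, leaving out each library, a test against a 2-fold change, and other list tests. Chosen after the data were seen were the authors' size factors as scaling and the fit without replicate 1 of both groups. No pair of libraries agreed within sampling noise, since the chi-square of counts over its degrees of freedom lay between 23.2 and 115 within groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.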

Results

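RNA was sequenced from Bacillus subtilis W168, a tryptophan-prototrophic laboratory strain of a Gram-positive soil bacterium. Cells grew in rich medium at 37 °C to an optical density of 0.5 and were split into 25 ml aliquots. SynAnt49, a synthetic compound for which the labels give a name but no structure, was added at 4 µg/ml for 10 min. There were 3 libraries from treated aliquots and 3 from untreated aliquots, and the untreated libraries are shared with another series of the same laboratory. Reads assigned to annotated genes numbered 5889386, 6292905 and 6731713 in untreated replicates 1 to 3, and 6438639, 6405118 and 6227224 in SynAnt49 replicates 1 to 3. The labels name the samples as replicates and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The comparison asks which transcripts differ between SynAnt49-treated and untreated cells. Fold changes are given as log2 of SynAnt49 over untreated, levels as TMM-scaled CPM (mean ± SD, n = 3 per group), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

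After 10 min of SynAnt49 the lia operon held the 2 largest fold changes of all rows tested. Transcripts of liaH, a phage-shock-type membrane protein, went from 24.5 ± 3.47 to 7741 ± 2557 CPM, and those of liaI, its membrane anchor, from 8.41 ± 2.46 to 2728 ± 920 CPM. The regulon of the envelope-stress sigma factor W rose in 52 of 54 genes, and the 12 genes of branched-chain amino acid synthesis and uptake all rose. In the list of peptidoglycan precursor and teichoic acid genes 19 of 35 fell and 4 rose, and of ribosomal protein genes 28 of 54 fell and 3 rose. With an estimated correlation none of these lists of sigma factor W, branched-chain, precursor and ribosomal protein genes kept its call (adjusted p = 0.504, 0.504, 0.504 and 0.855), but that setting had little ability to call any list. Fry, which asks whether a list moves at all, called the sigma factor W, branched-chain and precursor lists (adjusted p = 0.000609, 0.000596 and 0.000829). It did not call the ribosomal protein list (adjusted p = 0.0650). Of 4423 rows tested, 1948 (44.0%) changed, 1170 higher and 778 lower, and 1161 of them changed at least 2-fold (732 higher, 429 lower). In 2360 rows (53.4%) the 3 SynAnt49 values did not overlap the 3 untreated values, against 10% by chance. The split into higher and lower depends on the scaling, because library totals alone gave 891 higher and 1005 lower and upper-quartile scaling gave 835 higher and 1209 lower. These scalings moved log2 fold changes by a median of -0.22 and -0.31, so values near 0 below are best read against the median of all tested genes, 0.04.

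The LiaR regulon, controlled by the LiaFSR system that answers antibiotics acting on the lipid II cycle, rose in 9 of 9 genes (9 adjusted over the list alone), with a median log2 fold change of 3.49. The list test gave an adjusted p of 8.64e-06, and adjusted p = 0.617 with an estimated correlation. The log2 fold change was 8.33 (SE 0.38, adjusted p = 1.83e-07) for liaI (BSU33130, minus strand, 3398550 to 3398930 on the Bacillus subtilis 168 reference chromosome) and 8.30 (SE 0.37, adjusted p = 1.83e-07) for liaH (BSU33120, minus strand, 3397846 to 3398523). Downstream in the same operon, liaG rose by 4.72 and liaF, an inhibitor of the signalling pathway, by 4.14. The members outside the operon, yhcY, yhcZ and yhdA, rose by 0.61, 0.64 and 0.60 and were named after their values were seen. The count of the list was 6 of 9 under upper-quartile scaling, under library totals and without untreated replicate 2, and 7 without SynAnt49 replicate 2 or SynAnt49 replicate 3.

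Of the sigma factor W regulon, which covers envelope stress and detoxification, 52 of 54 genes rose and 0 fell (52 and 0 adjusted over the list alone), with a median of 2.73. Its list test gave an adjusted p of 4.37e-23, and adjusted p = 0.504 with an estimated correlation. The sigW gene itself (BSU01730, plus strand, 194849 to 195412) went from 308 ± 25.9 to 1610 ± 98.2 CPM, a log2 fold change of 2.39 (adjusted p = 1.31e-06). The operon of floT (BSU31010, minus strand, 3180465 to 3181994), which encodes a flotillin of membrane microdomains, showed log2 fold changes of 6.21 for floT, 6.22 for yuaF and 6.04 for yuaI. Other members with small p-values were yrhH (3.77), yxjI (4.68), yoaF (3.30) and racX (3.55), an amino acid racemase. The members that did not pass the test were ywbO (-0.09) and efeO (0.32), named after their values were seen.

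Sigma factor M genes, many of them for cell wall synthesis and division, moved both ways: 23 of 40 rose and 7 fell (25 and 10 adjusted over the list alone), with a median of 0.76. The list test gave an adjusted p of 0.00441, and adjusted p = 0.698 with an estimated correlation. The sigM gene rose by 1.13 (adjusted p = 0.000131), bcrC, an undecaprenyl pyrophosphate phosphatase, by 1.92, ypbG by 3.18, yqjL by 3.24 and sasA, a small alarmone synthetase, by 2.88. The operons of sigma factors Y and V rose in 5 of 11 genes and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.72, an adjusted p of 0.0134, and adjusted p = 0.694 with an estimated correlation. Among them were ybgB (2.04), sigV (1.64), rsiV (1.66), the anti-sigma factor of sigma factor V, and oatA (0.67), a peptidoglycan O-acetyltransferase. The remaining member that rose was yxlC (0.72), of the sigma factor Y operon, named after its value was seen. The sigma factor M list had 11 lower genes without untreated replicate 1, 3 without SynAnt49 replicate 2, 13 under upper-quartile scaling and 12 under library totals. The sigma factor Y and V list lost its call without SynAnt49 replicate 1 (median 0.46), without replicate 1 of both groups, under DESeq2 and under a stricter count filter, had 9 higher genes without SynAnt49 replicate 3, and had 3 under upper-quartile scaling, where oatA did not pass the test (0.36).

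Transporter modules that sense bacitracin and other peptide antibiotics were not called in the list test (adjusted p = 0.623). Of the 7 genes of the peptide detoxification modules 0 rose and 0 fell (0 and 0 adjusted over the list alone), among them the bacitracin transporter genes bceA (-0.21, adjusted p = 0.534) and bceB (-0.28, adjusted p = 0.218) and the lantibiotic transporter genes psdA (-0.10) and psdB (-0.35, adjusted p = 0.0715). The psdB difference passed the test without untreated replicate 1 (-0.48), without SynAnt49 replicate 1 (-0.49) and under library totals (-0.57), among 9 settings in all, and bceB passed it under upper-quartile scaling (-0.59) and a stricter count filter (-0.45). The sigma factor X list had 4 higher and 9 lower genes of 18 (4 and 9 adjusted over the list alone) and a list adjusted p of 0.0708, and sigX stood at -0.23 (adjusted p = 0.228), which passed the test under upper-quartile scaling (-0.54) and the stricter filter (-0.40). That list was called lower without untreated replicate 1 and without replicate 1 of both groups, and had 5 lower genes without untreated replicate 2, untreated replicate 3 or SynAnt49 replicate 2. Its 4 higher genes, named after their values were seen except yrhH (3.77), were efeB (0.98), rapD (0.71) and abh (1.17). Of these, yrhH, efeB and abh are also in the sigma factor W list, so their rises do not single out sigma factor X. The list of secretion stress (CssRS) and cell wall turnover (WalRK) genes split, with 7 of 17 higher and 6 lower (8 and 6 adjusted over the list alone) and a list adjusted p of 0.959. It was called higher under fry (adjusted p = 0.0294). In it, htrA, a membrane-anchored quality control protease, rose from 74.4 ± 12.3 to 762 ± 159 CPM, a log2 fold change of 3.36 (adjusted p = 7.57e-07). The cell wall hydrolase genes lytE (BSU09420, plus strand, 1018998 to 1020002) and cwlO (BSU34800, minus strand, 3574363 to 3575784) fell, with log2 fold changes of -3.84 (SE 0.22, adjusted p = 5.25e-07) and -2.77 (SE 0.27, adjusted p = 1.52e-05). A further member, ydjM, fell by 3.31, while iseA, an inhibitor of such hydrolases named after its value was seen, rose by 4.85.

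**Figure D1:**
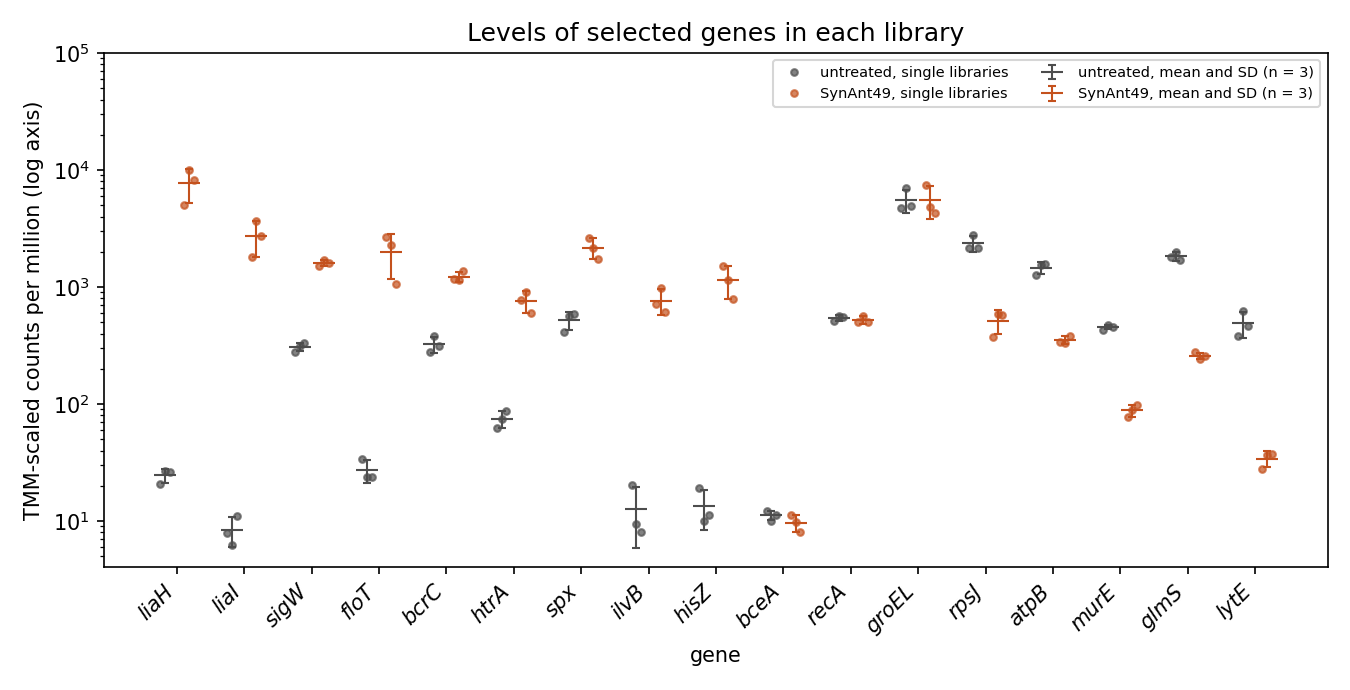
TMM-scaled CPM (log axis) of 17 genes in the 3 untreated (grey) and 3 SynAnt49 (orange) libraries, with dots for single libraries, horizontal marks for group means and whiskers for the SD (n = 3). The liaH values lie between 20.6 and 26.9 in untreated libraries and between 4998 and 10059 in SynAnt49 libraries, whereas the groups overlap for bceA, recA and groEL.

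Genes for peptidoglycan precursors and wall teichoic acid fell in 19 of 35 cases and rose in 4 (21 and 4 adjusted over the list alone), with a median of -0.83. The list test gave an adjusted p of 2.08e-05, and adjusted p = 0.504 with an estimated correlation. Transcripts of glmS (BSU01780, plus strand, 200277 to 202079), the glucosamine-6-phosphate synthase that feeds the pathway, went from 1833 ± 164 to 258 ± 16.5 CPM, a log2 fold change of -2.83 (SE 0.17, adjusted p = 6.59e-07). The murE, mraY and murD genes for lipid II precursor synthesis fell, with log2 fold changes of -2.37, -2.12 and -2.00. The 4 members that rose, named after their values were seen, were pbpH (1.51), for a penicillin-binding protein, the precursor genes murB (1.32) and murG (1.02), and gtaB (0.68), which makes UDP-glucose.

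Many genes of branched-chain amino acid and histidine synthesis rose. The branched-chain list, regulated by the nutritional repressor CodY and by uncharged transfer RNA, had 12 of 12 genes higher (12 adjusted over the list alone) and a median of 5.54. Its list adjusted p was 1.90e-09, and adjusted p = 0.504 with an estimated correlation. Transcripts of ilvD (BSU21870, minus strand, 2300762 to 2302438), dihydroxyacid dehydratase, went from 21.8 ± 0.358 to 2108 ± 674 CPM, a log2 fold change of 6.59 (SE 0.30, adjusted p = 1.83e-07). In the ilv-leu operon the values were 5.91 for ilvB, 6.34 for ilvC, 5.93 for leuA, 5.40 for leuC and 5.29 for leuD. The arginine, histidine and tryptophan list had 20 of 25 genes higher and 0 lower (21 and 0 adjusted over the list alone), a median of 2.11 and an adjusted p of 8.73e-07, and adjusted p = 0.504 with an estimated correlation. Histidine operon genes led it, with 6.42 for hisZ (BSU34930, minus strand, 3588185 to 3589360), 5.85 for hisG and 6.05 for hisD, followed by the chorismate pathway genes aroF (2.77) and aroB (2.63). The library medians of that list were 1.28 in SynAnt49 replicate 1, 2.36 in replicate 2 and 2.48 in replicate 3. Without SynAnt49 replicate 1 the median was 2.24 and the hisD value 5.42.

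The cysteine and methionine list was not called (adjusted p of 0.174), with 16 of 37 genes higher and 5 lower (16 and 5 adjusted over the list alone). It was called higher under DESeq2, under fry, without untreated replicate 1 and without replicate 1 of both groups. The 5 lower genes, named after their values were seen, were metK (-1.59), for S-adenosylmethionine synthetase, the methionine transporter genes metP (-1.41), metQ (-0.43) and metN, which went from 291 ± 49.6 to 146 ± 5.73 CPM, and the cystine transporter gene tcyP (-1.53). Outside the list yxjG (BSU38960, plus strand, 3999350 to 4000486), a putative methionine synthase gene, rose from 24.1 ± 3.50 to 1658 ± 346 CPM, a log2 fold change of 6.10 (adjusted p = 1.83e-07). A close paralog, yxjH, lies directly upstream on the same strand, so reads can have been split between them and the value of each is uncertain.

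Ribosomal protein genes were lower as a group, with 28 of 54 fallen and 3 risen (29 and 3 adjusted over the list alone) and a median of -0.84. The list test gave an adjusted p of 5.86e-07, and adjusted p = 0.855 with an estimated correlation. Fry did not call the list (adjusted p = 0.0650). The library medians were -1.64 in SynAnt49 replicate 1, -0.63 in replicate 2 and -0.56 in replicate 3, so replicate 1 stood apart. The median of the list was -0.67 without it. The first gene of the large ribosomal protein cluster, rpsJ (BSU01150, plus strand, 135364 to 135672), fell from 2364 ± 356 to 515 ± 120 CPM, a log2 fold change of -2.20 (SE 0.23, adjusted p = 1.99e-05). Other named members fell less, with -1.82 for rpsF, -1.68 for rpmH and -1.67 for rpsR. The 3 that rose, named after their values were seen, were rplI (0.39), rpmGA (0.79) and ypfD (0.97), a gene similar to that of ribosomal protein S1. The number of higher genes in the list was 1 when untreated replicate 2, untreated replicate 3, SynAnt49 replicate 2 or SynAnt49 replicate 3 was left out, and 1 under upper-quartile scaling, library totals or thinning to equal depth. Translation factors fell in 10 of 19 cases and rose in 1 (11 and 1 adjusted over the list alone), with a median of -0.41 and an adjusted p of 0.00805, and adjusted p = 0.855 with an estimated correlation and 0.0730 under fry. The ribosome recycling factor gene frr stood at -1.52, ylxS, for a ribosome maturation factor, at -1.34, the GTPase gene ylaG at -1.81 and yphC, for another GTPase, at -1.04. The 1 that rose was ysxC (1.07), a ribosome assembly GTPase gene named after its value was seen. Leaving out untreated replicate 2, untreated replicate 3 or SynAnt49 replicate 2 left 5, 6 and 5 translation factor genes lower.

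The ATP synthase and respiration list fell in 20 of 36 genes and rose in 1 (20 and 1 adjusted over the list alone), with a median of -0.61. Its adjusted p was 5.86e-07, and adjusted p = 0.504 with an estimated correlation. Within the ATP synthase operon atpI stood at -2.16, atpB at -2.04, atpF at -1.98 and atpH at -1.97, and atpB (BSU36870, minus strand, 3786878 to 3787612) went from 1454 ± 166 to 353 ± 25.9 CPM. The 1 member that rose was sdhB (0.50), of succinate dehydrogenase, named after its value was seen. The list had 0 higher genes when any single library was left out, under each other scaling and count filter and under DESeq2. The cytochrome bd gene cydA stood at -0.05 (adjusted p = 0.929).

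Purine genes were lower in 13 of 24 cases and higher in 1 (13 and 1 adjusted over the list alone), with a median of -0.57 and an adjusted p of 6.46e-04, and adjusted p = 0.698 with an estimated correlation. The largest falls were those of transporter genes: nupG (purine nucleosides, -2.96), pbuG (hypoxanthine and guanine, -2.93), pbuX (xanthine, -2.53) and pbuO (-2.01), and the efflux gene pbuE fell by 1.63. The 1 member that rose was guaB (1.04), for the first step of GMP synthesis, named after its value was seen. The pyrimidine list was not called (adjusted p of 0.793), with 1 of 10 genes higher and 3 lower (1 and 4 adjusted over the list alone). Its pyrR and pyrP genes, for the attenuator protein and uracil permease, fell, with log2 fold changes of -3.03 and -2.79, but their untreated levels were spread, 720 ± 355 and 770 ± 630 CPM. Without untreated replicate 1 pyrP stood at -2.17 (adjusted p = 0.0176) and the median of the list turned from -1.10 to 0.77, with 4 genes higher. Without untreated replicate 3 there were 5 lower. There were 0 higher without untreated replicate 2 or 3 or SynAnt49 replicate 2 or 3. With all libraries kept, the library medians of the list were -0.19, 0.34 and 0.48 in SynAnt49 replicates 1 to 3. Over the other fits the median of the list ran from -1.65 to 0.94, so its direction is not settled. The other members that moved, named after their values were seen, were pyrB (-2.73) and pyrE (2.13).

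Osmotic and potassium genes were lower in 12 of 25 cases and higher in 4 (12 and 4 adjusted over the list alone), with a median of -0.59 and an adjusted p of 0.0283, and adjusted p = 0.504 with an estimated correlation. The glycine betaine uptake genes opuAA, opuAB and opuAC fell, with log2 fold changes of -2.30, -2.00 and -2.06, as did the mechanosensitive channel gene ykuT (-1.78). The 4 that rose were khtS (2.71), khtT (3.01) and khtU (2.40), for a potassium exporter, and ktrC (0.71), for potassium uptake, all named after their values were seen. The call was lost without untreated replicate 1, where the median was -0.16, and without replicate 1 of both groups (-0.20). It was also lost without untreated replicate 2 (-0.61) or SynAnt49 replicate 1 (-0.55), and under upper-quartile scaling, library totals and a stricter count filter. Motility and chemotaxis genes were lower in 19 of 55 cases and higher in 3 (19 and 3 adjusted over the list alone), with a mean of -0.25, a median of -0.04 and an adjusted p of 0.0283, and adjusted p = 0.698 with an estimated correlation. The wall amidase operon genes lytB (-1.44) and lytC (-1.01) fell, as did the flagellar genes flhA (-1.22) and flhG (-1.15). In the run of neighbouring genes from flgB to swrB, every gene from fliP (-0.60) to swrB (-1.07) was lower. None from flgB to cheY was lower. This stretch was picked after its values were seen, and many of the lower genes of the list lie in it. The 3 that rose, named after their values were seen, were flgB (0.58), the first gene of the main flagellar operon, and the chemotaxis genes cheV (0.87) and mcpC (0.97); without SynAnt49 replicate 1 there were 5.

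Genes of the disulfide stress regulator Spx rose in 20 of 26 cases and fell in 1 (21 and 1 adjusted over the list alone), with a median of 1.25 and an adjusted p of 8.09e-06, and adjusted p = 0.698 with an estimated correlation. The spx gene itself rose by 2.05 (adjusted p = 2.74e-05), trxB (thioredoxin reductase) by 2.19, msrA (methionine sulfoxide reductase) by 2.05, yugP by 2.78 and yceC, which is also in the sigma factor W and M lists, by 3.37. The 1 member that fell was nfo (-0.89), a DNA repair endonuclease gene named after its value was seen. There were 2 lower without untreated replicate 1. General stress genes of sigma factor B rose in 40 of 80 cases and fell in 5 (40 and 5 adjusted over the list alone), with a median of 0.67 and an adjusted p of 0.00805, and adjusted p = 0.943 with an estimated correlation and 0.134 under fry. Library medians were 1.13, 0.75 and 0.12 in SynAnt49 replicates 1 to 3. The list lost its call without untreated replicate 1, which left 24 genes higher and 7 lower, without SynAnt49 replicate 1, which left 28 and 6, and without both, which left 20 and 8. In this list hpf, a ribosome hibernation factor gene, rose by 3.51, yjbC by 2.55, mcsA by 2.06 and sigB by 0.98 (adjusted p = 0.00534), which did not pass the test without replicate 1 of both groups (0.63). The yjbC gene is also in the sigma factor M list and mcsA in the protein quality control list, so their rises do not single out sigma factor B. The 5 lower genes, named after their values were seen, were rsbRD (-1.69), ywsB (-1.45), ydhK (-1.22), yhxD (-1.19) and katX (-0.89), and 3 were lower without untreated replicate 2 or SynAnt49 replicate 2. The classical sigma factor B target gsiB rose by 0.96 (adjusted p = 0.0461) with SynAnt49 levels of 400.0 ± 202 CPM, a call that was lost under all settings tried except the fit without a low-count filter and the fit without SynAnt49 replicate 3. Without SynAnt49 replicate 1 gsiB stood at 0.48.

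Protein quality control genes were divided, with 9 of 19 higher and 5 lower (9 and 7 adjusted over the list alone) and a list adjusted p of 0.793. The 5 lower genes, named after their values were seen, were yqeT (-1.94), yqeU (-1.91), yqeV (-1.61) and dnaJ (-1.46), of the dnaK operon, and ykoV (-1.21). The protease genes clpE and clpC, controlled by CtsR, rose by 1.70 and 1.57, whereas the chaperonin gene groEL stood at -0.01 (adjusted p = 0.991). DNA damage genes under LexA had 11 of 36 higher and 3 lower (11 and 3 adjusted over the list alone), with a list adjusted p of 0.780. They were called higher under fry (adjusted p = 0.00774). The recombinase gene recA (-0.05) and the division inhibitor gene yneA (0.61) did not pass the test. The 3 lower genes, named after their values were seen, were ypnP (-1.50), xkdA (-1.03) and pcrA (-0.83), and under upper-quartile scaling 11 were lower and recA was called (-0.36). The defective prophage PBSX had 9 of 32 genes higher and 1 lower (0 and 0 adjusted over the list alone), with a median of 0.41, an adjusted p of 0.0283, and adjusted p = 0.937 with an estimated correlation. The 1 lower gene was xkdA. There were 0 lower without untreated replicate 1 or 3 or SynAnt49 replicate 2 or 3. Values of 0.51 (xkdW), 0.48 (xtmA), 0.44 (xkdF) and 0.40 (xkdO) passed the test over all genes only, and under library totals or upper-quartile scaling 0 of its genes were higher. There were 2 without untreated replicate 1, and 0 without untreated replicate 2 or without any single SynAnt49 library. The list itself lost its call without untreated replicate 1, untreated replicate 2 or SynAnt49 replicate 3, under each other scaling and count filter, under DESeq2, with protein-coding genes alone, after thinning and under fry (adjusted p = 0.0650).

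The remaining lists were not called in the list test with the preset correlation. Quinone and aldehyde stress had 7 of 18 genes higher and 0 lower (7 and 0 adjusted over the list alone, list adjusted p of 0.111), and zinc, manganese and metal efflux 10 of 26 higher and 3 lower (10 and 3 adjusted over the list alone, list adjusted p of 0.121). Fry called both higher (adjusted p = 0.00611 and 0.0303), and the latter was called higher without untreated replicate 1 and without replicate 1 of both groups. Iron starvation genes split into 13 higher and 10 lower of 35 (13 and 10 adjusted over the list alone, list adjusted p of 0.793, called higher under fry with adjusted p = 0.0282), and peroxide genes into 7 and 3 of 16 (7 and 3 adjusted over the list alone, list adjusted p of 0.793). In the latter ahpC, alkyl hydroperoxide reductase, rose by 0.83 (adjusted p = 0.00723) and the catalase gene katA stood at 0.49 (adjusted p = 0.0951), which passed the test without SynAnt49 replicate 1 (0.56). Fatty acid genes were 2 higher and 6 lower of 22 (1 and 6 adjusted over the list alone, list adjusted p of 0.279); fabHB, for an initiating enzyme, rose by 1.95, and the desaturase gene des stood at 0.23 (adjusted p = 0.379). Biofilm matrix genes had 0 higher and 0 lower of 21 (0 and 0 adjusted over the list alone, list adjusted p of 0.0596), with a median of -0.34. The list was called lower under DESeq2 size factors (4 genes lower), the authors' size factors (5), protein-coding genes alone (5), no low-count filter (4), thinning to equal depth (5), leaving out untreated replicate 2 (6) and leaving out SynAnt49 replicate 3 (1). Upper-quartile scaling gave 7 lower genes without a call of the list. Among drug efflux and resistance genes 6 of 31 were higher and 5 lower (6 and 4 adjusted over the list alone, list adjusted p of 0.410), including bmrC (1.04) and bmrD (0.99), for an ABC transporter, and the ribosome protection gene vmlR (0.65, adjusted p = 0.0199), which rose. Leaving out untreated replicate 2, untreated replicate 3 or SynAnt49 replicate 2 ended the vmlR call, as did upper-quartile scaling (0.32), library totals (0.41) and a stricter count filter. Aminoacyl-tRNA synthetases had 6 higher and 5 lower of 23 (6 and 5 adjusted over the list alone, list adjusted p of 0.780), glycolysis and the citric acid cycle 7 and 4 of 30 (6 and 3 adjusted over the list alone, list adjusted p of 0.857), and fermentation 2 and 1 of 21 (2 and 1 adjusted over the list alone, list adjusted p of 0.793), with ldh at -0.33 (adjusted p = 0.279), which passed the test under upper-quartile scaling (-0.63). In these 3 lists the mean was above 0 while the median and the test pointed lower. Competence genes had 4 higher and 1 lower of 17 (4 and 1 adjusted over the list alone, list adjusted p of 0.793), phosphate starvation 2 and 1 of 19 (2 and 1 adjusted over the list alone, list adjusted p of 0.793), and cannibalism and antimicrobial peptides 2 and 4 of 24 (1 and 3 adjusted over the list alone, list adjusted p of 0.205). The alarmone synthetase gene relA stood at 0.48 (adjusted p = 0.0549) and sigY at 0.45 (adjusted p = 0.0957); relA passed the test without SynAnt49 replicate 1 (0.51) or replicate 1 of both groups and sigY without SynAnt49 replicate 3 (0.59).

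In these lists, members that moved against most others or were few were named after their values were seen. They were the zinc uptake genes znuB (-1.47) and znuC (-1.21) and the manganese efflux gene ydfM (-2.18), the peroxide regulon genes pfeT (-0.75), hemX (-0.65) and hemC (-0.40), and acpA (0.43), for acyl carrier protein. Of the efflux genes lmrB (-0.99), yfmO (-1.09), mdr (-0.65), bmrA (-0.58) and mdtP (-0.43) fell, and of the synthetase genes alaS (-1.10), thrS (-0.79), glyQ (-0.67), pheS (-0.59) and proS (-0.51). Central carbon genes that fell were gapB (-0.98), ptsG (-0.81), pdhA (-0.67) and pfkA (-0.55). Rises in hmp (2.18), for flavohemoglobin, and hemQ (1.69) stood beside a fall in the lactate permease gene lctP (-0.76). Competence genes that rose were ssbB (0.96), comFA (0.92), comFB (0.90) and dprA (0.63), and cinA fell (-1.11). In the phosphate list phoA (2.03), for alkaline phosphatase, and phoP (0.99) rose and glpQ (-1.86) fell, and among peptide genes sdpC (0.78) and sdpI (0.65) rose and bdbA (-1.82), sunT (-1.27), albE (-0.65) and albD (-0.62) fell. Counts in these lists moved with single libraries: without untreated replicate 1 there were 3 higher synthetase genes, 3 higher and 5 lower peroxide genes, 5 higher phosphate genes and 7 lower central carbon genes. Without untreated replicate 2 there were 3 lower synthetase, 2 lower competence, 3 lower fermentation, 6 lower iron, 1 lower central carbon, 1 lower quinone and 3 higher efflux genes. Without untreated replicate 3 there were 3 lower synthetase, 5 lower iron, 3 lower efflux and 4 higher peroxide genes. Without SynAnt49 replicate 1 there was 1 lower quinone gene. Without SynAnt49 replicate 2 there were 5 lower iron, 3 higher efflux, 4 higher peroxide, 2 lower synthetase, 2 lower peptide and 2 lower central carbon genes. The number of higher fatty acid genes was 1 without any single library but SynAnt49 replicate 3. That of higher peptide genes was 1 without any but untreated replicate 1.

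**Figure D2:**
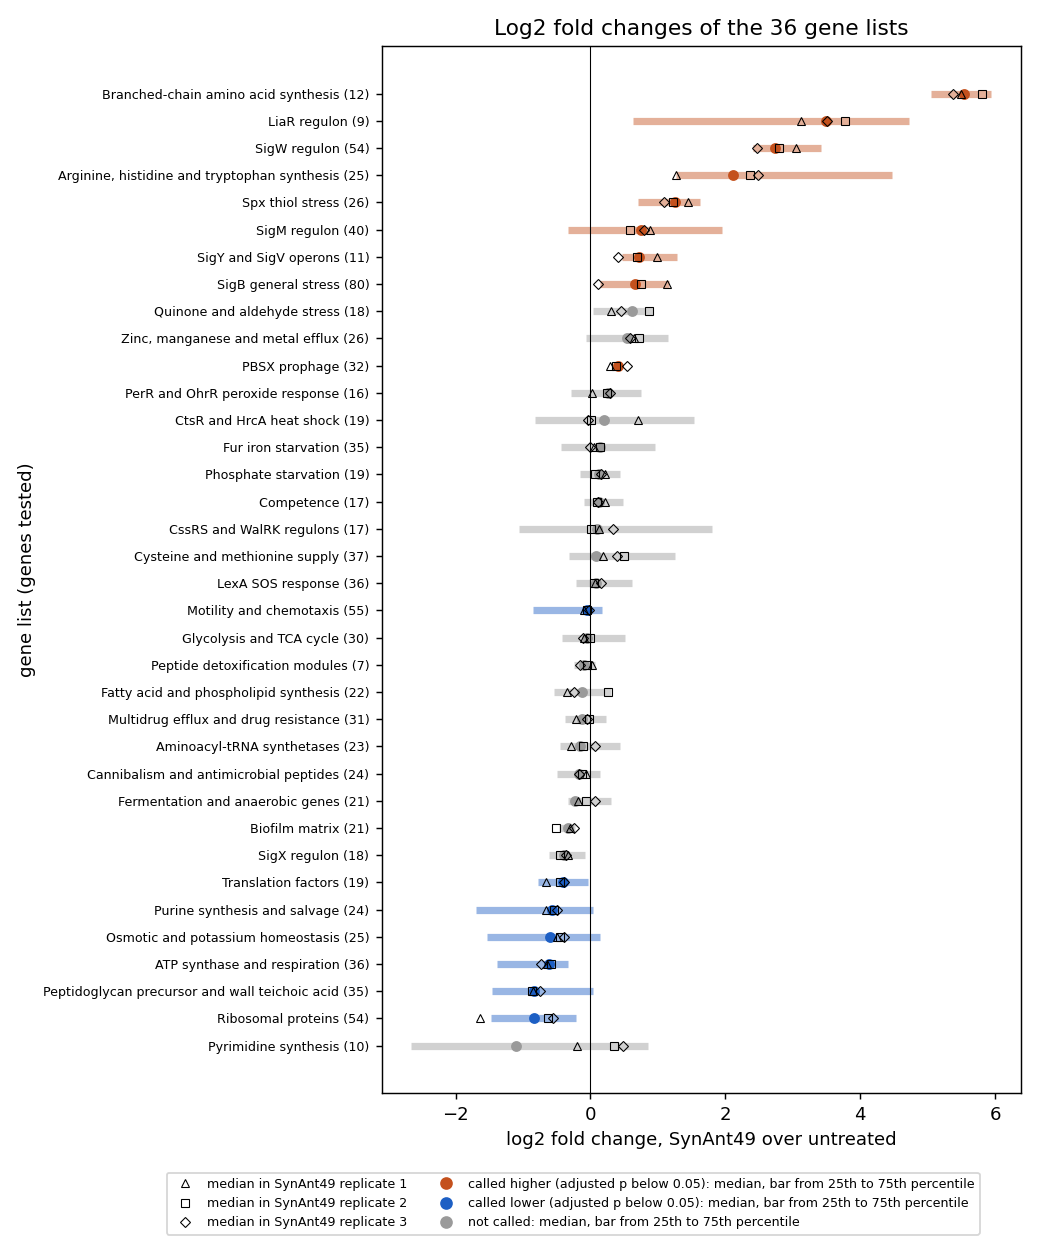
Median log2 fold change (SynAnt49 over untreated, horizontal axis) of each of the 36 gene lists, with bars from the 25th to the 75th percentile of its genes and open symbols for the median in each SynAnt49 library against the mean of the untreated libraries; orange and blue mark lists with an adjusted p below 0.05 in the list test with the preset correlation. The branched-chain list lies highest with a median of 5.54, and the ribosomal protein list spreads from -1.64 in SynAnt49 replicate 1 to -0.56 in replicate 3.

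Other large changes were falls in yxlA (-3.03), similar to purine-cytosine permease genes, yutK (-2.55), similar to nucleoside cotransporter genes, and yczE (-2.53). Of 563 annotated new RNA features tested, 99 were higher and 101 lower. The 3 with the largest change were S1499 (3999273 to 3999349, plus strand, log2 fold change 4.78), which ends directly upstream of yxjG, S1495 (3996377 to 3996599, plus strand, 4.43) and S658 (1917098 to 1917430, plus strand, 4.15).

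The authors' deposited table called 2035 genes, 1027 higher and 1008 lower in SynAnt49 once its sign was turned to SynAnt49 over untreated. Of the 4423 rows tested here, 1787 were called in both with the same direction, 0 with opposite directions, 222 in the authors' deposited table only and 161 here only. Across genes, which are not independent replicates, the log2 fold changes correlated with a Pearson coefficient of 0.9999 and a Spearman coefficient of 0.9999, and values here lay higher by a median of 0.12.

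With 16 of 36 lists called at the preset correlation, 9 higher and 7 lower, 0 were called with an estimated correlation, where the lowest adjusted p was 0.504. Other splits of the 6 libraries into 3 and 3 called up to 18 lists and 0 genes. Each of them placed untreated and SynAnt49 libraries together, so the treatment difference enters both sides and these counts do not show what chance gives. The untreated libraries were sequenced in 2 runs and the SynAnt49 libraries in 1 of these on another lane, with 0 combinations of run and lane shared, so no value within a lane can be given and sequencing and treatment cannot be told apart.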

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

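The scaling by the authors' size factors and the fit without replicate 1 of both groups were chosen only after the results were seen; the other alternatives were planned. Over all of them the number of changed genes ran from 1605 to 2044 (1948 as reported, edgeR), and the number of called lists from 13 to 17 under other fits. DESeq2 called 1826 genes and limma-voom 1940. Leaving out 1 library at a time gave 1605 to 1941 genes, 1103 to 1207 genes changed at least 2-fold and 13 to 16 lists, with SynAnt49 replicate 2 setting the lowest gene count and SynAnt49 replicate 1 the lowest list count. Testing directly against a 2-fold change with glmTreat left 646 genes (433 higher, 213 lower) in place of 1161, because that test asks for more than a change from 0 with a size filter. Camera with the estimated correlation called 0 lists in place of 16, and 0 at an unadjusted threshold of 0.05, since the lowest unadjusted p of camera in limma was 0.0529; fry, which asks whether a list moves at all, called 18 in one direction and 33 in either. Of 93 named genes that were called, 85 kept their call under each of the 18 fits, as did 12 of 16 lists under these fits; the lists that did not were SigB general stress, SigY and SigV, PBSX, and osmotic and potassium homeostasis. No called value changed sign, and 34 values that were not called did. Settings moved log2 fold changes of genes tested in both fits by a median of -0.31 with upper quartile, -0.22 with library totals, -0.16 with a stricter count filter, -0.13 with protein-coding genes only, -0.12 with the authors' size factors, -0.11 after thinning to equal depth and -0.11 without SynAnt49 replicate 1. The share of higher among called genes fell from 60.1% to 40.9% with upper quartile and 47.0% with library totals, as these scalings moved log2 fold changes down by the medians given above. Why the scalings differ was not tested. With the replicate number as a replicate block 1909 genes were called (1156 higher, 753 lower) and 17 lists; the biofilm matrix list, katA and relA were called there and gsiB, xkdW and xkdO were not. The residuals of same-numbered libraries correlated by 0.0627, 0.0205 and 0.0214, too little to pair them, and untreated replicate 2 correlated better with SynAnt49 replicate 3 (0.0403) than with its own number, as did untreated replicate 3 with SynAnt49 replicate 2 (0.022). Leaving out ribosomal and transfer RNA was not run, because no row of these kinds was counted. With 5889386 to 6731713 counts per library, genes near the floor of 0.446 to 0.509 CPM in both groups were left out by the expression filter and not tested in the main fit. A large rise from a low untreated level could be called, as for S1499 (1.45 ± 0.651 to 40.9 ± 1.59 CPM).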

Other observations

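All tests of gene order in operons, the genes named in the next paragraph and the tests on genes selected by their SynAnt49 levels were chosen only after the results were seen; the other tests were written before the result they measure.

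Among 2874 tested protein-coding genes in none of the 36 lists, 757 rose and 469 fell. Of these, sndC went from 23.0 ± 1.52 to 843 ± 228 CPM (log2 fold change 5.20). The oligopeptide permease gene oppA rose from 198 ± 30.6 to 4670 ± 814 CPM (4.56), aroA, for the first step of the chorismate pathway, from 745 ± 92.3 to 12256 ± 2041 CPM (4.04), and pspA, for a phage-shock protein related to LiaH, from 72.7 ± 6.11 to 1265 ± 283 CPM (4.12). The bacilysin gene bacG (4.01) and the aspartokinase gene lysC (3.93) rose as well. Among the falls were genes of polyamine synthesis: speA (-2.24), speB (-2.39) and speE (-2.21). The glycerol-3-phosphate permease gene glpT (-2.32) and the diguanylate cyclase gene dgcK (-2.39) fell too.

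Fold changes were graded along several runs of neighbouring genes, of which 3 were picked after their values were seen. In the ribosomal protein cluster from rpsJ to rplQ (31 genes) they went from -2.20 at rpsJ to 0.06 at rplQ, with a Spearman correlation with gene order across genes, which are not independent replicates, of 0.967 (0.973, 0.956 and 0.959 in SynAnt49 replicates 1 to 3); from atpI to atpC (9 genes) it was 0.950 (0.617, 0.950 and 0.983), and from flgB to swrB (32 genes) it ran the other way, -0.827 (-0.761, -0.798 and -0.848). Of 12 other long runs pyrB to pyrE (8 genes, 1.0) and hisZ to hisI (8 genes, -0.976) were graded as strongly. Uneven recovery along transcripts could give a gradient of 1 direction in long runs, but the median correlation in the 12 was 0.087 (95% bootstrap interval -0.29 to 0.345), which holds the bound of 0.3, so this stays open. That genes near the start of a lowered transcript fall first may be another explanation, and in 3 other lowered runs, 1 of them positive, the median was -0.214 (-0.367 to 0.667), too few to decide.

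Ribosomal protein genes were lower in SynAnt49, most in replicate 1 (median -1.64 against -0.63 and -0.56). The call of the list was lost in camera with an estimated correlation (0.727, adjusted p = 0.855) and under fry (adjusted p = 0.0650). With genes so correlated, intervals that treat genes as independent are too narrow. Gene dosage near the replication origin is not enough as an explanation, since each gene was set against 50 genes at the same distance and the list still lay lower (median difference -0.9003, 95% bootstrap interval -1.20 to -0.463, treating genes as independent). Library composition, taken as a shift of all genes alike, does not account for a gap between the list and other genes. The list lay below the median of all genes by more than the bound of 0.2 (-0.9628, -1.31 to -0.704, treating genes as independent). No scaling of totals can change that gap, so it restates the difference of the list and is no separate test of composition. Sequencing runs cannot be told apart from treatment, with 0 combinations of run and lane shared by both groups. A response to SynAnt49 may be the explanation, as a hypothesis that these data do not separate from sequencing runs.

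Untreated replicate 1 held more counts in weakly expressed genes: in 186 genes selected by low SynAnt49 levels it had 3.03 CPM per kilobase against 1.68 and 1.76 in the other untreated libraries, an excess of 1.31 (95% bootstrap interval 1.09 to 1.55). Genomic DNA could give an excess that is higher near the replication origin, but the ratio of the excess near the origin to that near the terminus was 0.741 (-0.904 to 2.40) with 6 genes near the origin, which decides nothing. Wrong-strand reads from annotated genes are argued against. The excess beside expressed opposite-strand genes was 1.315 times that in genes with no counts in annotated opposite-strand features (0.887 to 1.95, below the bound of 3). Opposite-strand reads outside annotated features were not counted, so the test does not cover them. Both tests were first run on 257 genes selected as low in untreated replicates 2 and 3, which raises the excess by itself; those ratios, 2.132 (0.935 to 3.694) and 1.102 (0.867 to 1.39), decide nothing, although an interval holding 1 had been set beforehand to exclude genomic DNA. No biological explanation was tested for a single library.

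With 6 libraries split into 3 and 3 there are 10 splits, too few to give a share under 0.05. The real split called 1948 genes and the highest other 0, so 1 of 10 splits reached that number; for changes of at least 2-fold it called 1161 and the highest other 0, again 1 of 10. For lists it called 16 and the highest other 18, and 3 of 10 splits called as many. Every other split held libraries of both groups on each side. Treatment then widens the spread within sides, which by itself can leave 0 genes, while part of the treatment difference stays between sides. These counts therefore do not measure what chance alone would give, for genes or for lists.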
